A study of Mus musculus with 20 samples.

How the data were processed

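Messenger RNA levels were measured in whole brains of 20 C57BL/6J mice, 5 in each combination of 2 ages (8 weeks, called young, and 2 years, called aged) and 2 genotypes. The genotypes were wild type and deficient for the alpha7 subunit of the nicotinic acetylcholine receptor, called alpha7-deficient. Per the labels' protocols, total RNA was extracted with TRI Reagent, purified on RNeasy columns, labelled with biotin and hybridised to Affymetrix arrays, 1 array per brain. The deposited values are linear signal intensities per probe set, made with MAS5 per the submitters' processing notes. The version of MAS5, its scaling target and any filter are not given in the sources used here. In the values themselves, the mean of each array's probe sets after trimming 2% at each end was 250 on every array. Groups came from the genotype and age in the labels. Replicate numbers were assigned in accession order, so they name an array and pair nothing.

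The table held 45101 probe sets, of which 64 were controls. By the platform annotation given with the data, 34945 named 1 gene symbol, 932 named several and 9160 named none. The gene identifiers of 34741 of the 34945 were found in a reference gene table of GRCm38.p6, and 0 symbols had to be updated. Only probe sets with 1 symbol entered the tests by gene. Values were taken to log2 without an added constant. Probe sets were kept when their mean log2 over the 20 arrays reached the 40th percentile of all non-control probe sets, a log2 of 5.45 or a signal of 43.6, which left 27022. The probe set with the highest mean log2 stood for its gene, so 13389 of 18193 genes were tested. The number of arrays limits the precision, and no detection calls were used.

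Differences were tested in limma 3.58.1 (R 4.3.3) with a model of 4 group means over all 20 arrays, lmFit and eBayes with an intensity trend, and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. The comparisons were age within each genotype, age averaged over genotypes, genotype at each age, genotype averaged over ages, and the difference between the age effects. Fold changes are 2 years over 8 weeks, or alpha7-deficient over wild type, on the log2 scale, with limma's standard error (SE). Age effects within the 2 genotypes share no array. RNA quality was measured as the log2 ratio of 3' to 5' control probe sets of Gapdh and beta-actin, tested by permutation (100000 resamples, two-sided, 10 arrays against 10).

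A set of 33 gene lists was fixed before the data were examined and tested with limma's camera (preset correlation 0.01, two-sided), with camera under an estimated correlation and fry beside it. The immune lists were microglia, aged and disease-associated microglia, complement, interferon response, antigen presentation, NF-kB and cytokine genes, B and plasma cells, T cells, and blood. The lists for brain cells were astrocytes, mature oligodendrocytes and myelin, oligodendrocyte progenitors and newly formed oligodendrocytes, immature neurons and proliferation, endothelium and pericytes, glutamatergic synapse, GABAergic neurons and receptors, cholinergic neurons and receptor partners, and nicotinic subunits. Lists of cell functions were collagens and extracellular matrix, activity-regulated genes, oxidative phosphorylation, cholesterol synthesis, circadian clock, heat shock and chaperones, and antioxidant and stress response. Lists for regions or adjoining tissue were choroid plexus, meninges and fibroblasts, pituitary, striatum, cerebellum, olfactory bulb and hypothalamus, and sex genes served as a check. The lists held 517 tested genes, and some genes stood in more than 1 list.

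The named genes were chosen by a rule written at the same time. It took Chrna7 and the measured nicotinic subunits, the 12 largest rises and 12 largest falls among the genes called with age averaged over genotypes, and every gene called for genotype. Clone symbols were skipped. From each list it took the 3 members with the smallest adjusted p for age where the list passed its test, and otherwise 1. The check genes for sex completed the 79 named genes. Other genes named below were chosen after their values were seen.

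The linear model and list test were tested on simulated data with 200 of 13389 genes changed by 1.5-, 2- or 4-fold. For age averaged over genotypes the model recovered 79.1%, 92.5% and 100% of them, and for genotype averaged over ages 77.6%, 97.0% and 100%. For the difference between age effects it recovered 28.4%, 64.2% and 89.4%. These shares hold for 200 changed genes. In the real data each genotype comparison called 1 gene, where the adjustment is stricter. The shares therefore do not give the recovery in those comparisons. Between 0.820% and 5.67% of the calls were false. The list test called the 1 shifted list and 0 of the others, on noise without correlation between genes.

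Alternatives tried were quantile normalization, a floor at the 25th percentile (a signal of 23.3), no filter and a filter at the 60th percentile, every probe set with 1 gene, and no probe sets of the kinds marked as shared between transcripts. Others were eBayes without trend, array weights, only the groups compared, Xist or the 3'/5' ratio as a covariate, leaving out the 3 animals whose number in the labels lies far from the rest, and leaving out each array in turn. Added after seeing the data were a term for those 3 animals, leaving out the 2 arrays with the highest 3'/5' ratio, those 5 arrays together, or the 2 arrays with the highest Gh and Prl, a test of every probe set, unnamed ones included, and the nicotinic list without Chrna7. Each count and list was also set against 100 splits of the arrays into groups of the same sizes. These splits, and the count per list, were run after the results they test were seen. Random splits often put several lists past camera's preset correlation, so the estimated correlation and the splits are given beside it. Figures and permutation tests used Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene order around Chrna7 was taken from the start positions in the GRCm38.p6 table, in which 13360 of the 13389 tested genes had a chromosome. Distances in bases were not used.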

Results

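Whole-brain expression profiles were compared between young (8 weeks) and aged (2 years) mice that were wild type or deficient for the alpha7 subunit of the nicotinic acetylcholine receptor, a ligand-gated cation channel opened by acetylcholine. Each of the 4 groups held 5 mice, and each brain was hybridised to its own array. After scaling to a common trimmed mean, the median signal per array lay between 61.3 and 78.96, and pairs of arrays correlated at r = 0.929 to 0.982 across probe sets. No pair shared more than 0.00665% identical values, so all 20 arrays were kept as separate samples. The first principal component held 19.5% of the variance between arrays and the second 11.8%. The 3 animals whose numbers in the labels lie far from the rest, young wild-type replicate 5 and aged alpha7-deficient replicates 1 and 2, had the lowest scores on the second component (-28.5, -23.9 and -22.3). They also had the 3 lowest median signals (61.3, 66.0 and 62.3). Numbers of the other young animals all lay above those of the other aged animals. A batch that follows the animal numbers can therefore not be told apart from age. Xist, the transcript that silences an X chromosome in female cells, lay at a log2 of 9.92 or more on 9 arrays and between 6.23 and 6.98 on the other 11. The 9 arrays were 2 of 5 in young wild type, 3 of 5 in aged wild type, 3 of 5 in young alpha7-deficient and 1 of 5 in aged alpha7-deficient mice. They were thus unevenly spread, most of all for genotype at 2 years and for age in alpha7-deficient mice. With Xist level as a covariate these 2 comparisons called 1 and 1814 genes, against 1 and 1967 without it.

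Chrna7, which encodes the alpha7 subunit, was lower in both alpha7-deficient groups. Its log2 signal (probe set 1440681_at) was 8.77 ± 0.29 in young and 8.60 ± 0.10 in aged wild-type brains, against 5.75 ± 0.47 and 5.47 ± 0.15 in the alpha7-deficient brains (SD, n = 5 each). Averaged over ages it fell by 3.08 (SE 0.127, adjusted p = 2.2e-13), and at each age by 3.02 and 3.13 (SE 0.180). A weaker probe set, 1450299_at, lay below the filter at a mean log2 of 3.93 and differed by -0.78 (SE 0.440, unadjusted p = 0.0917). Where each probe set lies relative to the deleted part of the gene is not given in the sources used here. No other nicotinic subunit that was tested passed for genotype or age. Chrna1, Chrna2, Chrna5, Chrna9, Chrnb3, Chrnd, Chrne and Chrng lay below the filter and were not tested. Chrnb2 and Chrna4, the subunits of the main high-affinity nicotinic receptor of the brain, differed between genotypes by 0.06 (SE 0.0981) and 0.15 (SE 0.113). Chrna6, a subunit of dopaminergic neurons, differed by -0.41 (SE 0.278), Chrnb1 by 0.23, Chrnb4 by -0.31 and Chrna3 by -0.06. Single arrays moved these values by over 1.5 times. Chrna6 went to -0.13 without aged alpha7-deficient replicate 2, Chrnb1 to 0.48 without replicate 5 of that group and Chrnb4 to -0.57 without aged wild-type replicate 2. Leaving out any 1 array, Chrna3 ranged from -0.10 to 0.0058, Chrnb2 from -0.0025 to 0.10, Chrna4 from 0.07 to 0.19, Chrnb1 from 0.12 and Chrnb4 up to -0.12.

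**Figure D1:**
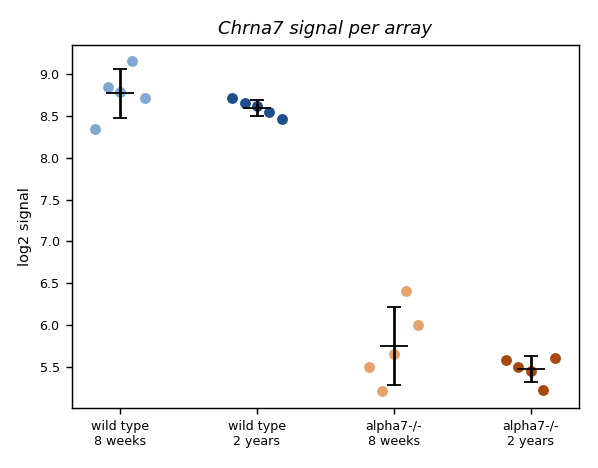
Log2 signal of Chrna7 on each of the 20 arrays, by group, with group means and SDs (n = 5 per group). Wild-type means are 8.77 (8 weeks) and 8.60 (2 years), and alpha7-deficient means are 5.75 and 5.47.

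The comparison of genotypes asked what the loss of the alpha7 subunit changes in the brain transcriptome at each age. Chrna7 was the only gene that limma called, at 8 weeks, at 2 years and averaged over ages. At an unadjusted p under 0.05 the 3 tests passed 695, 777 and 469 genes, against 669 expected by chance. Activity-regulated genes, transcription factors and effectors induced by neuronal firing, stood higher in alpha7-deficient mice as a list. Their mean log2 difference was 0.45 over ages, 0.65 at 8 weeks and 0.26 at 2 years. Of the 22 genes none passed the test over all genes, and 9 did when adjusted over the list alone, in the average over ages (7 at 8 weeks and none at 2 years). Examples are Fos at 1.01 (SE 0.294), Arc at 1.21 (SE 0.399) and Egr2 at 1.09 (SE 0.298). The list passed camera averaged over ages (adjusted p = 1.2e-16), but not with an estimated correlation (adjusted p = 0.190 with an estimated correlation). At 2 years (adjusted p = 0.0171) its call was lost without any 1 of 4 arrays, aged replicates 1 and 2 of either genotype (adjusted p = 0.0689 to 0.231), and its mean turned to -0.02 without the 3 animals with distant numbers.

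The pituitary list, which holds hormone genes and others such as Ghrhr and Chga, stood lower in alpha7-deficient mice. Its mean was -1.08 over 7 genes (camera adjusted p = 8.1e-04; adjusted p = 0.381 with an estimated correlation). None of the 7 was called over all genes, and 1 was lower when adjusted over the list alone. Gh, growth hormone, spread over a log2 range of 10.7 between single arrays and Prl, prolactin, over 10.6. The mean over ages was -0.71 without aged wild-type replicate 3 and -0.43 without that array and young wild-type replicate 1, the 2 arrays with the highest Gh. At 8 weeks this list's call was lost without young wild-type replicate 1 (mean -0.82 against -1.38, adjusted p = 0.159). Collagens and extracellular matrix genes had a mean difference of -0.12 (adjusted p = 0.00339; adjusted p = 0.311 with an estimated correlation), with 0 of 25 members called over all genes or adjusted over the list alone. The nicotinic list passed with 1 called member, Chrna7 (adjusted p = 0.00762; adjusted p = 0.190 with an estimated correlation), and did not pass without it (mean -0.06 against -0.49, adjusted p = 0.966). Another 5 lists passed camera over ages with mean differences between -0.08 and 0.12 and no called member. They were microglia, heat shock and chaperones, antioxidant and stress response, striatum and cerebellum, and their adjusted p with an estimated correlation lay between 0.505 and 0.837. Each of the 5 lost its call in 7 to 15 of the 20 fits that left out a single array, and the mean of the cerebellum list turned to -0.01 without young wild-type replicate 4. At 8 weeks 5 lists passed camera and at 2 years 9, and none did with an estimated correlation (adjusted p = 0.355 to 0.619 and 0.0921 to 0.802 with an estimated correlation). Genes near Chrna7, which can carry sequence of the strain in which an allele was made, were compared with the rest. Among the 200 tested genes on each side, 1.25% had an unadjusted p under 0.01 for genotype, against 0.502% of the others (two-sided Fisher's exact p = 0.0584). Among 100 genes on each side it was 2% (Fisher's exact p = 0.0208) and among 400 it was 0.875% (p = 0.197). The 5 genes within 200 were Iglon5, Trpm4, Mrgpra3, Nipa1 and Mcee, and none was called.

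The comparison of ages asked what 2 years of life change in the brain. Averaged over genotypes, Lyz1 rose by 2.85 (SE 0.217, adjusted p = 2.4e-08) and Lyz2 by 1.97 (SE 0.182), near-identical lysozyme genes that probe sets may not separate. Lgals3, a galectin of activated microglia, rose by 2.02 (SE 0.174, adjusted p = 2.1e-07) and Cd52, a leukocyte surface glycoprotein, by 1.85 (SE 0.211). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 2.06 (SE 0.220, adjusted p = 3.4e-06). On all 10 aged arrays these 5 genes lay above every young array. The others of the 12 largest rises were S100a8 (1.83), S100a9 (1.82), the vasopressin gene Avp (1.62), the interferon-induced GTPase gene Gbp6 (1.54), the lipid droplet coat genes Plin4 (1.49) and Plin3 (1.44), and Clec7a (1.47), a receptor for fungal glucans. On 3 aged arrays, wild-type replicate 4 and alpha7-deficient replicates 4 and 5, S100a8 lay at 9.71, 10.15 and 10.42 and S100a9 at 9.22, 9.98 and 9.83. On the other 7 aged arrays S100a8 lay between 5.73 and 7.86 and S100a9 between 5.24 and 7.41, against at most 6.35 and 6.42 on young arrays. S100a9, a neutrophil protein gene, had an adjusted p of 0.0391 and lost its call when any 1 of 7 arrays was left out (adjusted p = 0.0560 to 0.0791). Those arrays were young wild-type replicates 1 and 2, aged wild-type replicates 4 and 5, young alpha7-deficient replicate 3 and aged alpha7-deficient replicates 4 and 5.

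The largest falls with age included genes of immature cells and the extracellular matrix. Gpr17, a receptor of oligodendrocytes in formation, fell by 1.37 (SE 0.157, adjusted p = 8.1e-06) and Col3a1, a fibrillar collagen gene, by 1.35 (SE 0.148, adjusted p = 4.7e-06). Met, the receptor for hepatocyte growth factor, fell by 1.46 (SE 0.180, adjusted p = 2.0e-05). These 3 lay below every young array on all 10 aged arrays. Sox4 and Sox11, transcription factor genes of newborn neurons, fell by 1.04 (SE 0.115) and 1.08 (SE 0.180). The others of the 12 largest falls were the integrin gene Itga5 (-1.36), Dtl (-1.26), the glycosyltransferase gene B3galt1 (-1.21), Commd5 (-1.17), the Myc family gene Mycl (-1.16), the steroid dehydrogenase gene Hsd17b1 (-1.09) and Rfx2 (-1.002), a transcription factor gene of ciliated cells. Of these 24 genes, rises included, 8 had a group mean below the filter's log2 of 5.45, where signal was not shown to be above background, so the sizes of their changes depend on low signals. With low values floored their changes were 1.34 for Gbp6, 1.65 for S100a9, 2.005 for Lgals3, -1.07 for Itga5, -1.44 for Met, -1.11 for Mycl, -0.99 for Hsd17b1 and -0.87 for Rfx2, all still called. Across all genes 2348 of 13389 were called, 1221 higher and 1127 lower at 2 years, with 4296 at an unadjusted p under 0.05. Of the called genes 266 changed by at least 1.5-fold (156 up, 110 down) and 59 by at least 2-fold.

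**Figure D2:**
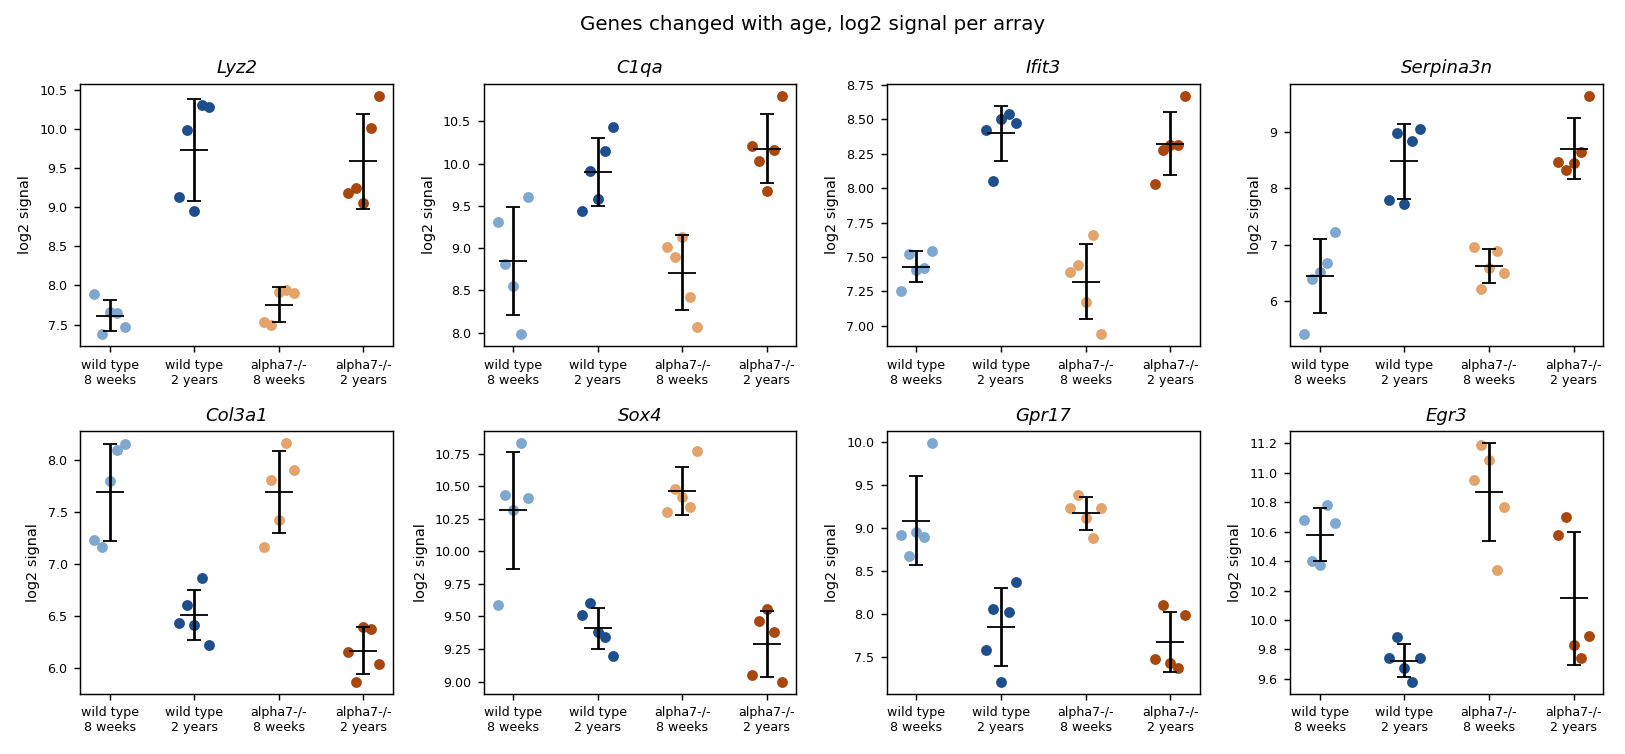
Log2 signal of 8 genes on each of the 20 arrays, by group, with group means and SDs (n = 5 per group). Lyz2, C1qa, Ifit3 and Serpina3n are higher at 2 years in both genotypes (averages of 1.97, 1.26, 0.98 and 2.06), and Col3a1, Sox4, Gpr17 and Egr3 are lower (-1.35, -1.04, -1.37 and -0.79).

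Of the 9 immune lists 6 passed camera with a mean rise, as did the astrocyte list, and 3 of these 7 also passed with an estimated correlation, while the lists of NF-kB and cytokine genes, B and plasma cells, T cells, myelin and oligodendrocyte progenitors did not pass. Of 25 interferon response genes 13 rose and 0 fell (16 rose when adjusted over the list alone), among them Ifit3 by 0.98 (SE 0.0960) and Ifi27 by 0.90 (SE 0.0839). Of 14 antigen presentation genes 10 rose (13 when adjusted over the list alone). They included the class I genes B2m, by 0.86 (SE 0.0905), and H2-K1, by 1.02 (SE 0.144), and the class II gene H2-Aa, by 0.74 (SE 0.0912). Among genes of aged and disease-associated microglia 11 of 15 rose (11 when adjusted over the list alone), such as Lgals3bp by 1.01 (SE 0.114). These 3 lists passed camera at adjusted p = 1.7e-11, 4.7e-10 and 4.6e-11 and held with an estimated correlation (adjusted p = 0.0353, 0.0323 and 0.0353 with an estimated correlation). General microglial markers rose in 11 of 19 cases (11 when adjusted over the list alone), including Tyrobp, an adaptor of microglial receptors, by 1.26 (SE 0.140) and the protease gene Ctss by 0.85 (SE 0.0949). Complement genes rose in 5 of 9 cases (5 when adjusted over the list alone), among them all 3 chains of C1q, with C1qa at 1.26 (SE 0.187), C1qc at 1.22 (SE 0.157) and C1qb at 1.07 (SE 0.159). The microglial and complement lists passed camera at adjusted p = 5.0e-09 and 3.1e-05, and did not with an estimated correlation (adjusted p = 0.118 and 0.0610 with an estimated correlation). Of 21 astrocyte genes 5 rose (7 rose and 1 fell when adjusted over the list alone), among them the filament genes Gfap by 0.91 (SE 0.155) and Vim by 0.37 (SE 0.0748). That list passed at adjusted p = 0.00184 (adjusted p = 0.334 with an estimated correlation), and its call was lost with quantile normalization (adjusted p = 0.0744). Blood genes rose in 3 of 5 cases (3 when adjusted over the list alone), S100a8 and S100a9, which stood high on 3 aged arrays, and Alas2, the erythroid enzyme of heme synthesis, at 1.12 (SE 0.307). The blood list passed at adjusted p = 0.0275 (adjusted p = 0.334 with an estimated correlation) and lost its call without aged alpha7-deficient replicate 5 (adjusted p = 0.0636), with either other filter or without shared probe sets (adjusted p = 0.0626 to 0.225).

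**Figure D3:**
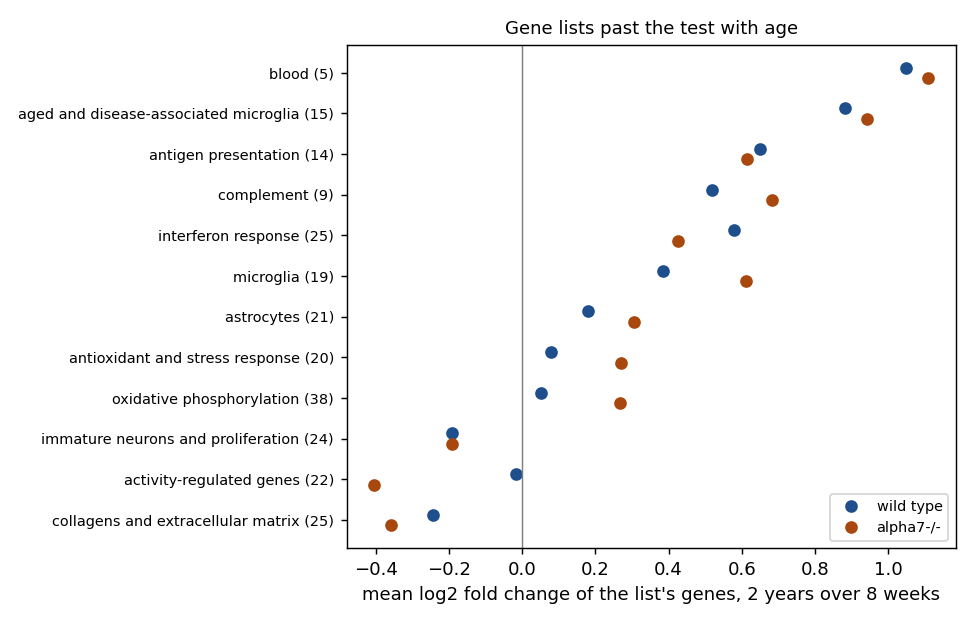
Mean log2 fold change with age (2 years over 8 weeks) of each gene list past camera averaged over genotypes, in wild-type and alpha7-deficient mice, with the number of tested genes in parentheses. Lists of aged and disease-associated microglia (0.88 and 0.94), interferon response (0.58 and 0.42) and antigen presentation (0.65 and 0.61) lie at similar values in both genotypes, and oxidative phosphorylation lies at 0.05 and 0.27.

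Lists of matrix genes, of immature neurons and of activity-regulated genes passed camera with mean falls, and none of the 3 passed with an estimated correlation. Of 25 collagen and extracellular matrix genes 9 fell and 1 rose (10 fell and 1 rose when adjusted over the list alone). Besides Col3a1 these included Nid1, a basement membrane protein gene, by -0.76 (SE 0.133) and Col25a1, a neuronal collagen gene, by -0.42 (SE 0.102). The riser was Sparc (0.44), a matrix protein gene. The list passed at adjusted p = 0.00103 (adjusted p = 0.118 with an estimated correlation). Of 24 genes of immature neurons and proliferation 7 fell and 1 rose (9 fell and 4 rose when adjusted over the list alone). Dpysl3, a growth cone protein gene, fell by 0.59 (SE 0.0784) and the cyclin gene Ccnd2 by 0.56 (SE 0.0899), while Pcna, a replication clamp gene, rose by 0.25. This list passed at adjusted p = 0.0251 (adjusted p = 0.0654 with an estimated correlation), and not without young wild-type replicate 5 (adjusted p = 0.0533). Activity-regulated genes, whose list mean was -0.02 in wild-type mice (median 0.04, adjusted p = 0.546) and -0.40 in alpha7-deficient mice, fell in 5 of 22 cases (6 when adjusted over the list alone), with Egr3 at -0.79 (SE 0.119), Nr4a3 at -0.72 (SE 0.139) and Bdnf, a neurotrophin gene, at -0.39 (SE 0.0804). Their list passed at adjusted p = 0.0154 (adjusted p = 0.633 with an estimated correlation), and its call was lost without young wild-type replicate 1 (mean -0.10 against -0.21, adjusted p = 0.2004).

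Lists of mitochondrial respiration and of antioxidant defence passed camera with small mean rises averaged over genotypes, and neither passed with an estimated correlation or in wild type. Oxidative phosphorylation stood at 0.05 in wild-type mice (adjusted p = 0.147, 0 of 38 genes called) and 0.27 in alpha7-deficient mice, and antioxidant genes at 0.08 (adjusted p = 0.179, 1 of 20 called) and 0.27. Of 38 oxidative phosphorylation genes 16 rose and 0 fell (20 rose when adjusted over the list alone). Examples are the ATP synthase gene Atp5a1 by 0.23 (SE 0.0473) and the complex I genes Ndufs7 by 0.38 (SE 0.0843) and Ndufv2 by 0.26 (SE 0.0605). The list's mean was 0.16 (adjusted p = 4.0e-08; adjusted p = 0.334 with an estimated correlation). With quantile normalization the mean dropped to 0.06 (adjusted p = 0.0442) and Atp5a1 was no longer called. Of 20 antioxidant and stress response genes 8 rose (9 rose and 2 fell when adjusted over the list alone). Il33, a nuclear cytokine gene, rose by 0.87 (SE 0.0760), Gstm1, a glutathione transferase gene, by 0.48 (SE 0.0891), and Gpx3, a glutathione peroxidase gene, by 0.43 (SE 0.0999). Gpx3 changed by -0.0024 in wild-type and 0.86 in alpha7-deficient mice (SE 0.141). In wild type Gstm1 lay between 11.10 and 11.21 on aged arrays, within the 10.59 to 11.54 of young ones. In alpha7-deficient mice it lay at 11.37 to 11.81 on aged and 10.73 to 10.90 on young arrays. That list passed at adjusted p = 0.00184 (adjusted p = 0.273 with an estimated correlation).

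Within each genotype the same test called different numbers of genes. In wild-type mice 103 genes were called with age, 65 higher and 38 lower, with 1714 at an unadjusted p under 0.05. In alpha7-deficient mice 1967 were called, 1047 higher and 920 lower, with 4103 at an unadjusted p under 0.05. Of the 103 wild-type calls 87 were also called in alpha7-deficient mice, all in the same direction, against 15.1 expected of independent lists, and all 103 had the same sign there. Of the alpha7-deficient calls 91.3% had the same sign in wild type. Lyz1 rose by 2.98 in wild-type and 2.73 in alpha7-deficient mice (SE 0.306), Serpina3n by 2.04 and 2.08 (SE 0.311), and Lgals3 by 1.87 and 2.17 (SE 0.246). Met fell by 1.18 and 1.74 (SE 0.255), and Gpr17 by 1.24 and 1.49 (SE 0.222). Across genes, which are not independent replicates, the age fold changes of both genotypes correlated at r = 0.471. Without the filter on dim probe sets r dropped to 0.269. Without the 3 animals with distant numbers the count in wild type was 250 and in alpha7-deficient mice 1059. Leaving out any 1 of the 10 wild-type arrays moved the wild-type count by over 1.5 times, to 244 and 169 without young replicates 1 and 5 and to between 45 and 68 without any of the other 8. Leaving out aged replicate 1 moved the alpha7-deficient count to 1117.

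**Figure D4:**
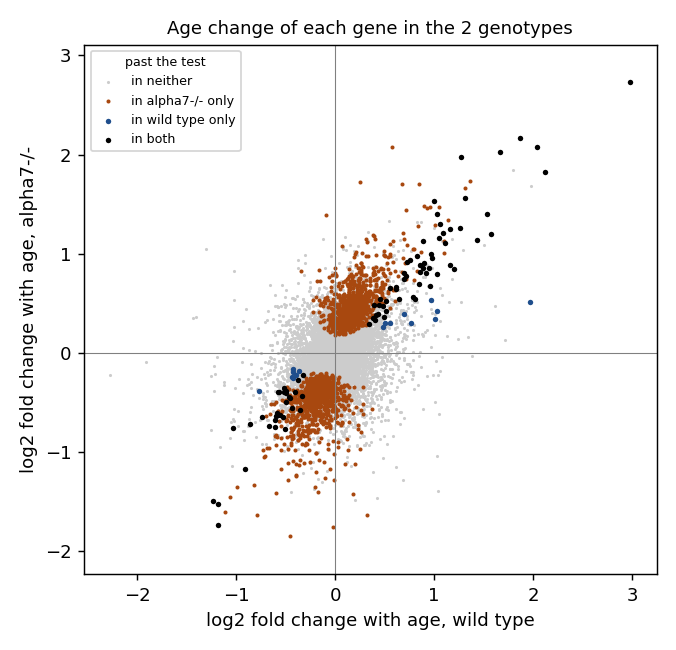
Log2 fold change with age (2 years over 8 weeks) of each of 13389 genes in wild-type mice (horizontal) against alpha7-deficient mice (vertical), coloured by the genotypes in which the gene was called. The 87 genes called in both lie in the same direction in both, 16 were called in wild type and not in alpha7-deficient mice, and 1880 the other way round.

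In wild-type mice the interferon response list rose with 6 of 25 members called (14 when adjusted over the list alone; camera adjusted p = 1.1e-17). Aged and disease-associated microglia had 6 of 15 (9 when adjusted over the list alone) and antigen presentation 4 of 14 (9 when adjusted over the list alone). Complement had 1 of 9 (4 when adjusted over the list alone). These 4 lists, the fall of immature neurons and proliferation (2 of 24, or 6 when adjusted over the list alone) and a rise of the circadian clock list (0 of 17, or 2 when adjusted over the list alone) also passed with an estimated correlation (adjusted p = 0.00914 to 0.0421 with an estimated correlation). The clock list's camera call was lost without the 2 arrays with the highest Gh and Prl (adjusted p = 0.0593 against 0.0101). Microglia (5 of 19 up, 8 when adjusted over the list alone), collagens (1 of 25 down, 3 when adjusted over the list alone) and blood (0 of 5, and 0 when adjusted over the list alone) passed camera but not with an estimated correlation (adjusted p = 0.164, 0.164 and 0.375 with an estimated correlation). The blood list's camera call was also lost without any 1 of 4 arrays, young wild-type replicates 1 and 3 and aged wild-type replicates 4 and 5 (adjusted p = 0.0694 to 0.141). In alpha7-deficient mice 13 lists passed camera and 0 with an estimated correlation (adjusted p = 0.145 to 0.639 with an estimated correlation). Among them, interferon response had 10 of 25 members up (12 when adjusted over the list alone), aged and disease-associated microglia 10 of 15 (10 up and 1 down when adjusted over the list alone) and oxidative phosphorylation 19 of 38 (29 up and 1 down when adjusted over the list alone). Without the 3 animals with distant numbers 3 of the 13 lists lost their call (collagens, cerebellum and hypothalamus) and that of endothelium and pericytes changed sign.

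The difference between the age effects was tested directly. With limma 0 genes passed, with the smallest adjusted p at 0.605 and 525 genes higher and 548 lower at an unadjusted p under 0.05. In simulated data with 200 of 13389 genes changed, on noise without correlation between genes, the same test recovered 64.2% of genes that differed by 2-fold. With fewer changed genes the adjustment is stricter, so this share does not give the recovery in the real data. Avp rose by 1.27 in wild-type and 1.98 in alpha7-deficient mice (SE 0.225), a difference that did not pass (adjusted p = 0.605). Without the filter 1 gene, Ppp1r32, passed, chosen here after its value was seen. As a list, oxidative phosphorylation genes had a mean age effect 0.22 higher in alpha7-deficient mice (camera adjusted p = 2.3e-11; adjusted p = 0.573 with an estimated correlation), with 0 of 38 members called over all genes or adjusted over the list alone. With quantile normalization this difference was 0.06 and no longer called (adjusted p = 0.123). It was 0.15 without young wild-type replicate 5, 1 of the 3 animals with distant numbers, 0.10 without all 3 (adjusted p = 2.0e-05) and 0.09 with a term for them (adjusted p = 1.5e-04). Another 8 lists passed camera for the difference and none did with an estimated correlation (adjusted p = 0.573 to 0.722 with an estimated correlation).

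RNA quality was compared between ages and between genotypes. The mean log2 3'/5' ratio of Gapdh and beta-actin was 1.75 ± 0.23 on aged and 1.85 ± 0.40 on young arrays (SD, n = 10 each; permutation p = 0.538). Between genotypes it was 1.77 ± 0.34 in alpha7-deficient and 1.83 ± 0.32 in wild-type mice (SD, n = 10 each; permutation p = 0.708). Means of the 4 groups, which were not tested against each other, ran from 1.72 to 1.94. The highest ratios were on young wild-type replicate 4 (2.65) and young alpha7-deficient replicate 5 (2.37). The next 3 were on the 3 animals with distant numbers, aged alpha7-deficient replicates 2 and 1 (2.22 and 2.06) and young wild-type replicate 5 (2.03).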

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

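Chosen only after the results were seen were the tests on other splits of the arrays (except the reassignments of genotype within age), the test of the 2 samples with the highest Gh, and the fits with a term for 3 animals and without the 2 arrays with the highest 3'/5' ratios. Among the named genes 16 of 316 pairs of a gene and a group held an array whose gap to its neighbour was above 0.71 of the group's range, the critical value for 5 samples. Chance alone gives this in about 1 in 20 groups, or 15.8 of these pairs. In young wild-type mice the shares were 0.830 for Ache (replicate 4, lowest), 0.782 for Gpr17 (replicate 5, highest) and 0.814 for Mycl (replicate 1, lowest). In aged wild-type mice replicate 2 was lowest for Chrnb4 (0.888), Ifit3 (0.767) and Sox11 (0.711). In young alpha7-deficient mice they were 0.856 for Gbp6 (replicate 4, lowest), 0.733 for Th (replicate 4, highest), 0.872 for Ifi27 (replicate 5, lowest) and 0.862 for S100a9 (replicate 3, lowest). In aged alpha7-deficient mice replicate 2 was lowest for Chrna6 (0.756) and Nid1 (0.717), and replicate 3 for Avp (0.790). Replicate 5 of that group was lowest for Chrnb1 (0.744) and highest for Serpina3n (0.760) and Xist (0.860). The median signal of young wild-type replicate 5, at 61.3 against 73.8 for its neighbour, gave a share of 0.7101.

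The age effect differed between genotypes for 9 lists by camera, and for 0 lists with an estimated correlation. The differences, alpha7-deficient minus wild type, were 0.22 for oxidative phosphorylation (adjusted p = 2.3e-11), 0.23 for microglia (adjusted p = 0.00815) and 0.13 for astrocytes (adjusted p = 0.0485). Antioxidant genes stood at 0.19 (adjusted p = 0.00352), the hypothalamus at 0.29 (adjusted p = 0.00223) and the olfactory bulb at 0.26 (adjusted p = 0.0485). Lower were the cerebellum at -0.54 (adjusted p = 2.9e-05), endothelium and pericytes at -0.43 (adjusted p = 0.00112) and activity-regulated genes at -0.39 (adjusted p = 0.00271). With an estimated correlation the adjusted p was 0.573 to 0.722. Without the 3 animals with distant numbers 3 of the 9 lists kept their call and direction, 5 lost their call and 1 changed sign, and with a term for them these numbers were 3, 4 and 2. Leaving out 1 array ended the call in 10 of 20 fits for astrocytes, 12 for the olfactory bulb and 3 for microglia (young wild-type replicate 5, aged wild-type replicate 3 or aged alpha7-deficient replicate 5). Without young wild-type replicate 5 astrocytes went to 0.043, microglia to 0.13 and antioxidant genes to 0.13. The cerebellum went to -0.27 without young wild-type replicate 4, endothelium and pericytes moved by over 1.5 times without any 1 of the 3 animals with distant numbers (to -0.24 without aged alpha7-deficient replicate 2), and activity-regulated genes went to -0.60 without young wild-type replicate 1. No member of the 9 lists was called over all genes by limma. Adjusted over the list alone, 1 activity-regulated gene was called lower, and 2 antioxidant, 1 olfactory bulb and 1 hypothalamus genes were called higher.

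Among probe sets without a gene name in the reference, which the gene tests leave out, 2 differed with genotype averaged over ages. Probe set 1421190_at was higher by 0.92 in alpha7-deficient mice (SE 0.109, adjusted p = 2.57e-04). Its means were 7.67 and 7.80 in young and aged wild-type mice, against 8.66 and 8.64 in young and aged alpha7-deficient mice. Probe set 1440557_at was lower, at -1.67 (SE 0.164, adjusted p = 1.36e-05), with means of 7.466, 7.502, 6.273 and 5.351 in the same order.

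More genes were called with age in alpha7-deficient mice (1967) than in wild-type mice (103), a ratio of 19.1. Without the 3 animals with distant numbers the ratio was 4.24, and with a term for them 4.15, both above the bound set for them. The fit with a term was chosen after the results were seen, so for it this bound was not set before them. That bound cannot exclude a batch of these animals as the whole cause. Other reassignments of genotype within age gave a median larger count of 868 and a median smaller count of 211. The part between 19.1 and 4.24 or 4.15 stays open as well. RNA quality of single arrays as the whole cause was argued against by ratios of 24.1 with the 3'/5' ratio as a covariate and 28.1 without the 2 arrays with the highest ratios, while array weights gave 5.54 (486 and 2694 genes) and leaving out these 5 arrays 7.55 (192 and 1449). An age effect that differs with genotype and differences between single animals cannot be told apart, because 8 of 100 reassignments of genotype within age gave a ratio as far from 1 and the direct test called 0 genes. Leaving out 1 array gave ratios from 8.42 (without young wild-type replicate 1) to 42.6 (without aged wild-type replicate 5). Fits with only the groups compared gave 53.2 (38 and 2020 genes).

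Signals of Gh and Prl spanned 10.7 and 10.6 log2 units over the 20 arrays, with Gh at 13.57 on young wild-type replicate 1 and 13.83 on aged wild-type replicate 3, and no biological explanation was tested. A shift of the arrays as a whole was argued against by its range alone, 0.37 for log2 median signal, since its rho with Gh of 0.377 (0.485 without the 3 animals with distant numbers) lay between the bounds of 0.2 and 0.6 set beforehand. Pituitary tissue on some samples cannot be told apart from other sources over all 20 arrays: Gh against the mean of 5 other pituitary genes gave rho = 0.579 (permutation p = 0.00898, adjusted over 3 relations 0.0135), below the 0.6 set beforehand, and rho = 0.755 without the 3 animals with distant numbers. The matching r = 0.874 (permutation p = 1.3e-04, adjusted 1.95e-04) rests on those 2 arrays, at r = 0.459 without them. On the 2 samples alone pituitary tissue is a candidate explanation, as 3 of the 5 other genes, Pomc, Lhb and Tshb, also had their 2 highest of 20 values there (binomial chance 1.4e-06). That chance takes the 5 genes as independent of each other, which was not shown, so it does not measure the strength of the evidence.

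Activity-regulated genes stood higher in alpha7-deficient mice averaged over ages, by a mean of 0.45, a call that was lost with an estimated correlation (adjusted p = 0.190). This cannot be told apart from differences between single animals: 4 of 100 reassignments of genotype within age gave a shift as large in size (highest other 0.56; 5 at 8 weeks, 32 at 2 years), too many for a list picked among 33, which the bound of 5 set beforehand did not allow for. RNA quality of single arrays as the whole cause was argued against by a shift of 0.44 with the 3'/5' ratio as a covariate. Without the 3 animals with distant numbers the shift was 0.28, and at 2 years alone it was -0.018 against 0.26, so part of it may lie with these animals. An effect of the genotype and an unrecorded difference in handling before tissue was taken both stay open, the latter untested.

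Other splits of the arrays, 100 per comparison with the real one included, tested whether chance can be excluded. For gene counts chance was excluded for age averaged over genotypes (1 split as large, real 2348, highest other 684), age in wild type (1, real 103, highest other 7) and age in alpha7-deficient mice (1, real 1967, highest other 2). These splits cannot tell age from a batch that follows the animal numbers. For genotype the real count was 1 gene, the targeted Chrna7. As a count it was matched in 4 splits at 2 years (highest other 2), under 5 of 100, in 7 at 8 weeks (highest other 29) and in 9 averaged over ages (highest other 5). These shares test a count of any 1 gene and say nothing against the call of Chrna7 itself (adjusted p = 2.4e-10, 5.0e-10 and 2.2e-13 in that order). For the difference between age effects the splits say nothing, since with a real count of 0 all 100 are as large (highest other 3). The split at 8 weeks with 29 genes points to a structure of the young samples, whose cause was not tested. It had on 1 side the 4 young arrays with the highest 3'/5' ratios (2.65, 2.37, 2.03 and 1.89) and young wild-type replicate 1. Chance was excluded for the correlation of age effects (1, real 0.471, highest other 0.320) and not for that of genotype effects (38, real -0.096, highest other in size 0.219). For the number of lists past camera chance was excluded in no comparison. These numbers were 12 for age averaged over genotypes (6 splits as large, highest other 14), 9 in wild type (30, highest other 16) and 13 in alpha7-deficient mice (7, highest other 14). For genotype they were 5 at 8 weeks (54, highest other 13), 9 at 2 years (33, highest other 18) and 9 averaged over ages (16, highest other 16), and for the difference 9 (28, highest other 14). List by list, under 5 of 100 splits shifted the mean as far for 11 of the 12 lists past camera with age averaged over genotypes, for 9 of 9 in wild type and 11 of 13 in alpha7-deficient mice. The exception among the 12 was activity-regulated genes (29). For genotype this held for 2 of 5 lists at 8 weeks, 4 of 9 at 2 years and 3 of 9 averaged over ages, and for 2 of 9 lists of the difference. Lists past camera had been picked by their shift on these same arrays, so these shares are not a separate test. Those at 2 years and averaged over ages include the nicotinic list, which holds the targeted Chrna7. Among all 33 lists, 4 had under 5 such splits in each genotype comparison and 2 in the difference. With age it was 13 averaged over genotypes, 9 in wild type and 15 in alpha7-deficient mice. The 13 include 2 lists that did not pass camera, oligodendrocyte progenitors (mean -0.20) and the circadian clock (0.12). For each of these 2 only 1 of 100 splits, the real one, was as large.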

How the results depend on the processing

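Alternatives chosen after seeing the data were a test of every probe set, a term for the 3 animals with distant numbers, and fits without the 2 arrays with the highest 3'/5' ratios, without these 5 arrays together and without the 2 arrays with the highest Gh and Prl. So was the nicotinic list without Chrna7, where its mean with genotype averaged over ages went from -0.49 to -0.058 and the test turned up, as its largest value was left out. No paired analysis was possible because the labels pair no animals, and replicate numbers were assigned in accession order. Chrna7 kept its fall averaged over ages, at -3.16 to -3.01 without any 1 array. The age count averaged over genotypes was 1882 to 3045 without any 1 array, with 11 to 14 lists past camera, and the correlation of age effects was 0.356 to 0.572. In the same fits genotype averaged over ages kept 1 gene and the difference between age effects 0. Of 66 named genes called with age 57 kept direction and call under all settings that tested them, leaving out 1 array included, 7 lost their call in some (S100a9, Neurod1, Ighm, Hsd17b1, Hspa4, Mycl and Atp5a1) and 2 reversed. The other 13 stayed uncalled, and 5 of them changed sign in some settings (Chga, Chrnb4, Kdm5d, Uty and Xist). With quantile normalization Ptgds and Ttr went to -0.0022 and -0.056 with age from 0.23 and 0.22, and the cause was not tested. With an estimated correlation 3 of the 12 lists passed for age averaged over genotypes, a construction that widens the test of correlated genes. Without the filter the correlation of age effects dropped from 0.471 to 0.269, as dim probe sets join, and the difference called 1 gene. Testing every probe set called 2 probe sets for genotype at 8 weeks, 2 at 2 years and 3 averaged over ages, of which 1, 1 and 2 have no gene name. Genotype at 8 weeks also called 2 genes with eBayes without trend (adding Cox8b) and with only the groups compared (adding Slc8a3). At 2 years it called 2 with arrayWeights, without the 3 animals and without the 5 arrays (adding Appbp2os, like the others chosen after its value was seen). The count with age in wild type was 486 with arrayWeights, 38 with only the groups compared, 250 without the 3 animals, 216 with a term for them, 64 without the 2 arrays with the highest 3'/5' ratios and 192 without the 5. In alpha7-deficient mice it was 1059 without the 3 animals and 897 with a term. Lists reversed in the same fits. Endothelium and pericytes went from -0.35 to 0.14 with age in alpha7-deficient mice without the 3. The same list went from -0.31 with genotype at 2 years to 0.18 without the 3 or the 5 and 0.13 with the term. In the difference it went from -0.43 to 0.24, 0.22 and 0.23 in that order. Activity-regulated genes with genotype at 2 years went from 0.26 to -0.018 without the 3 or the 5. In the difference, astrocytes went from 0.13 to -0.013 with the term, and the cerebellum from -0.54 to 0.034 without the 5. The cerebellum with genotype averaged over ages went from 0.12 to -0.021 without the 2 arrays with the highest 3'/5' ratios. For these counts and lists the cause was not tested. Among 100 genes on each side of Chrna7 2% had an unadjusted p under 0.01 for genotype and 0 were called (Fisher's exact p = 0.0208), against p = 0.0584 with 200 and 0.197 with 400. Leaving out 1 array gave 45 to 244 genes with age in wild type, moved over 1.5 times by each of the 10 wild-type arrays (244 without young replicate 1, 169 without young replicate 5, 45 to 68 without each other). It gave 1117 to 2378 with age in alpha7-deficient mice (1117 without aged replicate 1). Genotype gave 1 to 2 genes at 8 weeks (2 without young wild-type replicate 1, adding Dusp1) and 1 to 2 at 2 years (2 without aged alpha7-deficient replicate 1, adding Appbp2os). The cerebellum with genotype averaged over ages ranged from -0.014 (without young wild-type replicate 4) to 0.19. Signal over background limits genes near the filter, and no detection calls were used here to mark which were above it.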

Other observations

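Chosen after the results were seen were the test of the clock list without 2 arrays and the genes named as examples. For age averaged over genotypes 21 lists did not pass camera, several with members called in both directions. Of 19 myelin genes 3 rose and 5 fell (5 and 5 when adjusted over the list alone; adjusted p = 0.760; median 0.04, mean -0.06). Ugt8a, an enzyme gene of myelin lipids, fell by 0.82 (SE 0.125), Tspan2 by 0.70 (SE 0.0810) and Cldn11, a tight junction gene, by 0.70 (SE 0.0885), while Apod, a lipid carrier gene, rose by 0.75 (SE 0.105). Of 19 genes of oligodendrocyte progenitors 2 rose and 5 fell (2 and 7 when adjusted over the list alone; adjusted p = 0.170), with Gpr17 at -1.37 and Pdgfra, a growth factor receptor gene, at -0.48. Of 22 glutamatergic and synaptic genes 2 rose and 4 fell (4 and 5 when adjusted over the list alone; adjusted p = 0.509; median 0.00, mean -0.01). Homer1, a scaffold gene, fell by 0.34 (SE 0.0674) and Grm5 by 0.31, and Vamp2, a vesicle fusion gene, rose by 0.24. Of 18 GABA genes 2 rose and 2 fell (2 and 3 when adjusted over the list alone; adjusted p = 0.863), with the vesicular transporter gene Slc32a1 at 0.40 (SE 0.0663) and the receptor subunit gene Gabra2 at -0.49. Of 20 cholesterol synthesis genes 2 rose and 3 fell (3 and 4 when adjusted over the list alone; adjusted p = 0.622), with Cyp51 at -0.45 (SE 0.0738). Of 17 clock genes 4 rose and 2 fell (5 and 2 when adjusted over the list alone; adjusted p = 0.0882). Bhlhe40 rose by 0.49 (SE 0.0994) and the repressor gene Cry2 by 0.29, and the activator genes Arntl and Clock fell by 0.40 and 0.34. In wild type alone the clock list passed camera (adjusted p = 0.0101), and not without the 2 arrays with the highest Gh and Prl (adjusted p = 0.0593).

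No regional or vascular list passed camera for age averaged over genotypes. Across all tested genes 17.5% were called in that comparison. Of 14 hypothalamus genes 3 rose and 1 fell (3 and 1 when adjusted over the list alone; adjusted p = 0.0876), with Avp at 1.62 and Crh, a stress hormone gene, at -0.49. Of 11 olfactory bulb genes 3 rose (4 when adjusted over the list alone; adjusted p = 0.316), among them Th, the enzyme gene of dopamine synthesis, by 0.57 (SE 0.112). In wild type Th lay between 7.73 and 7.99 on aged arrays, within the 7.31 to 8.36 of young ones. In alpha7-deficient mice it lay at 8.13 to 8.44 on aged and 7.12 to 7.73 on young arrays. The direct test did not call this difference over all genes. Of 16 cerebellum genes 1 fell (5 when adjusted over the list alone; adjusted p = 0.172). This was Neurod1 at -0.46 (adjusted p = 0.049; 0.03 in wild-type and -0.95 in alpha7-deficient mice), whose call was lost without any 1 of 15 arrays (adjusted p = 0.0600 to 0.0970) and kept without young wild-type replicates 4 and 5 or aged alpha7-deficient replicates 3, 4 and 5. Of 13 striatum genes 1 fell (1 when adjusted over the list alone; adjusted p = 0.944; median 0.01, mean -0.02), Pde10a at -0.46. Of 19 genes of endothelium and pericytes 3 fell (3 when adjusted over the list alone; adjusted p = 0.0882), Itm2a by 0.60 (SE 0.101), Slco1c1, a thyroxine transporter gene, by 0.61 and Acta2 by 0.51. Of 18 choroid plexus genes 1 rose and 2 fell (1 and 2 when adjusted over the list alone; adjusted p = 0.697), and of 18 meningeal genes 1 rose and 1 fell (1 and 1 when adjusted over the list alone; adjusted p = 0.731; median -0.03, mean 0.08). The risers, Ttr at 0.22 and Ptgds at 0.23, changed sign with quantile normalization. Of 12 NF-kB and cytokine genes 2 rose and 1 fell (2 and 1 when adjusted over the list alone; adjusted p = 0.861), with Tlr2 at 0.46 and Ptgs2 at -0.45. Of 22 heat shock and chaperone genes 2 fell (1 when adjusted over the list alone; adjusted p = 0.861; median 0.03, mean 0.02, with the test pointing down). Of 4 B cell genes 1 rose (1 up and 1 down when adjusted over the list alone; adjusted p = 0.794), Ighm at 0.67 (SE 0.188). By limma no gene was called, over all genes or over the list alone, among 7 nicotinic receptor genes (adjusted p = 0.315), 12 cholinergic genes (adjusted p = 0.863), 7 pituitary genes (adjusted p = 0.863), 3 T cell genes (adjusted p = 0.731) and 3 sex genes (adjusted p = 0.989; median -0.13, mean -0.05, with the test pointing up). Xist and Kdm5d of the sex list lay on opposite sides on single arrays. Their log2 signals were 10.50 and 4.43 on young wild-type replicate 1, and 6.98 and 7.88 on replicate 2. Such values can cancel in a mean, so the mean of this list cannot show whether the sexes were balanced between groups. Single arrays can: Kdm5d lay at 5.55 or less on the 9 arrays with high Xist and at 6.86 or more on the other 11. By these 2 genes the groups were not balanced. High Xist was found on 3 of 5 arrays in aged wild-type and 1 of 5 in aged alpha7-deficient mice.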
